A study of Bos taurus with 10 samples.

How the data were processed

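Endometrial cytobrush samples of 10 cows were measured by RNA sequencing, 7 infused with bacteria and 3 with saline, and grouped by the sample titles. Per the labels' protocols, RNA was extracted with an RNeasy kit, mRNA was captured with poly-T beads and cDNA was made with random hexamers. The protocol describes both a strand-marking and an unmarked library, so the strand of these reads is not known and overlapping or antisense genes are uncertain. Per the submitters' processing notes the tools were CASAVA, HISAT2 2.0.5 and featureCounts 1.5.0-p3; the genome build and annotation are not given in the sources used here. The authors deposited raw read counts per gene and FPKM values in 1 table with a column of each for every library. The authors' FPKM values were used only to look at scaling: the library total they imply was 0.838 to 1.16 times the sum of counts. Gene symbols were taken from the table, and from the reference table of assembly ARS-UCD2.0 where a listed symbol was absent; 31299 gene IDs (90.1%) matched it. Only 49.1% of the matched starts were equal, so no coordinates were taken from it.

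Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, scaled by TMM, and fitted with robust glmQLFit and tested by glmQLFTest with group as the term, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM, counts scaled to the library total, used TMM-scaled library sizes, and log2 CPM a prior count of 2. The standard error of a log2 fold change is its size divided by the square root of F. The common biological coefficient of variation was 0.547. Library totals of 15566378 to 21293914 counts make 1 count between 0.0470 and 0.0642 CPM before scaling. Intervals of shares and floors of 3 counts cover counting error only, since the reads carry no molecular identifiers.

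Before the data were examined, 20 gene lists, 15 marker lists and a rule for the genes named were fixed. The rule takes, where fewer than 12 genes pass in a direction, up to 6 per direction by smallest p, given as values, up to 4 members per list that pass or else 2 with the smallest p, and 11 fixed genes. The conceptus genes and the interferon-stimulated genes given per library, except ISG15 and MX1, were chosen after their values were seen. Lists were tested by camera on voom values with a preset correlation of 0.01, with an estimated correlation, by fry, and by a two-sided exact permutation test over the 120 splits of 10 libraries into 7 and 3 of the mean log2 CPM. The share of variance between groups was tested over the same splits. The smallest p these splits allow is 0.00833, which for a single list becomes 0.167 adjusted over 20 lists and 0.125 over 15.

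The alternatives were RLE, upper quartile and total-count scaling, no filter and a stricter filter, DESeq2 1.42.0, voom with and without sample quality weights, no robust fit, glmTreat at 1.5-fold, a threshold of 0.1, each of 10 libraries left out, a replicate block in cows 1 to 3 of each group, a surrogate variable from sva 3.50.0, and marker levels as covariates. Leaving out bacteria replicates 2 and 4 together, removing a lowess trend (span 0.3) of log2 CPM on gene length, the permutation test of lists, and the list tests in cows 1 to 3 of each group without the block were added after the data were seen. The tests were checked on counts simulated from these libraries' means, sizes and dispersions with 200 changed genes. A simulated list of 50 genes raised 2-fold had a camera adjusted p of 4.19e-31. The simulated genes were independent of each other, so this checked the computation, not how often camera with a preset correlation calls unchanged lists of correlated genes. Chance was examined over 100 of the 120 splits drawn with a fixed seed.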

Results

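The transcriptome of endometrial cells taken with a cytobrush was measured in 10 cows at day 41 of the experiment, which fell on day 16 of the estrous cycle. On day 0 the uterus of 7 cows had been infused with Escherichia coli strain MS499 and Trueperella pyogenes strain MS249, and the uterus of 3 cows with phosphate-buffered saline. Each cow gave 1 library. The total read count per library lay between 15566378 and 21293914. In units of 1e6 counts it averaged 18.8 ± 2.32 (SD, n = 7) after bacteria and 17.0 ± 0.780 (SD, n = 3) after saline. Of 34750 genes in the table, 15930 had enough counts to be tested. No pair of libraries agreed within sampling noise, as the lowest chi-square per degree of freedom of any pair was 61.6.

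The comparison asked whether an induced uterine infection left a mark on the endometrium at the time of the cycle when a conceptus would elongate. The genes with the smallest p that were higher after bacteria included PYCARD (gene ID 282846), the inflammasome adaptor, and GSDMD (gene ID 513939), the pore-forming protein of pyroptosis. PYCARD had 16.8 ± 3.85 CPM (SD, n = 7) after bacteria and 3.60 ± 1.05 CPM (SD, n = 3) after saline, a log2 fold change of 2.21 (SE 0.32). GSDMD had 18.9 ± 4.71 CPM (SD, n = 7) and 5.59 ± 1.36 CPM (SD, n = 3), a log2 fold change of 1.76 (SE 0.28). JDP2, a repressor of AP-1 transcription, had a log2 fold change of 2.14 (SE 0.29) and EPHX2, the soluble epoxide hydrolase, of 1.44 (SE 0.22). The potassium channel gene KCNQ5 had 3.30 (SE 0.51) and CCDC190 2.58 (SE 0.37). KCNQ5 lay near the floor after saline, at 0.268 ± 0.0382 CPM (SD, n = 3), so its fold change rests on a few counts per saline library. On the lower side stood REV3L (gene ID 517422), the catalytic subunit of DNA polymerase zeta, with 27.0 ± 3.73 CPM (SD, n = 7) after bacteria and 53.8 ± 0.856 CPM (SD, n = 3) after saline. Its log2 fold change was -0.995 (SE 0.148). LPIN1, a phosphatidate phosphatase of lipid synthesis, had a log2 fold change of -1.29 (SE 0.23), ZNF462 of -1.23 (SE 0.19), the receptor phosphatase gene PTPRM of -1.08 (SE 0.18), ZNF217 of -0.96 (SE 0.17) and TRIO of -0.89 (SE 0.15). In each of these 12 genes the values of the 7 cows given bacteria and the 3 cows given saline did not overlap. They were picked by their p in these same data, so their lack of overlap is no further support. Over all tested genes 727, or 4.56%, had groups that did not overlap, against 1.67% by chance on average. Genes are not independent of each other, and how far this share varies between splits was not computed.

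**Figure D1:**
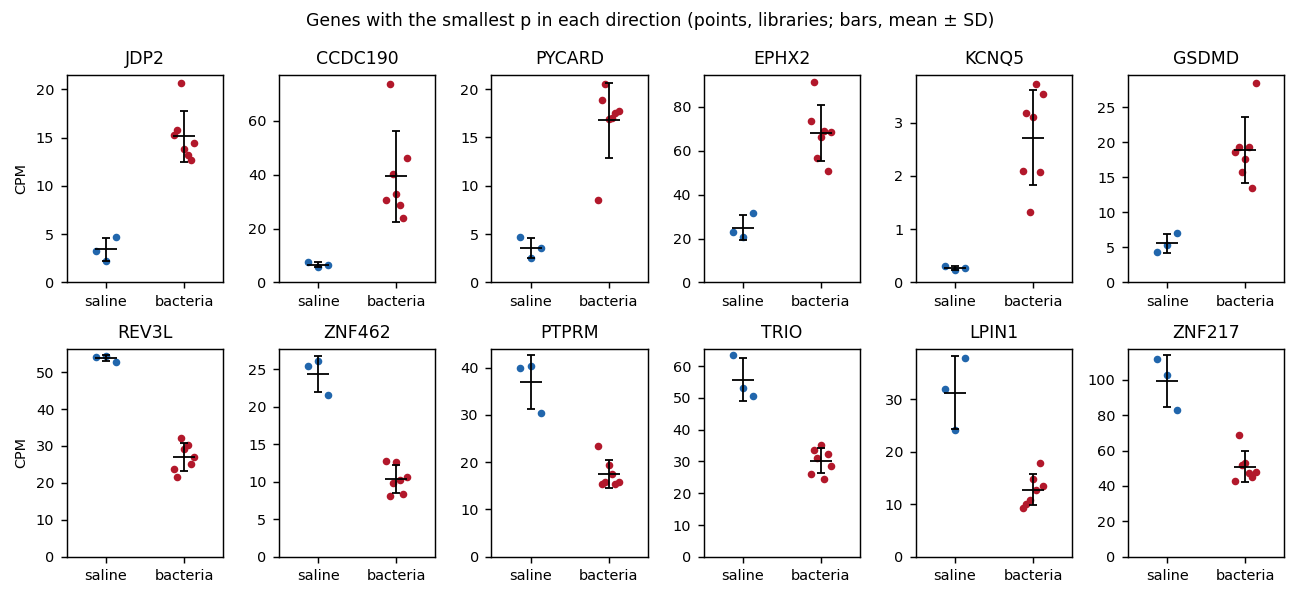
CPM (counts scaled to the library total) of the 6 genes with the smallest p in each direction, 1 point per library, with the mean and SD of 3 saline and 7 bacteria libraries. In all 12 genes every bacteria library lies on one side of every saline library; PYCARD averages 16.8 CPM after bacteria and 3.60 CPM after saline.

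None of these genes passed the test. With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 0 of 15930 genes had an adjusted p under 0.05. The smallest adjusted p was 0.0937, shared by genes that included JDP2, CCDC190, PYCARD, EPHX2, KCNQ5, GSDMD, REV3L and ZNF462. At an adjusted p under 0.1 there were 11 genes, 9 higher and 2 lower. That count was 1 without bacteria replicate 1 or bacteria replicate 2 and 0 without each of the other libraries. It was also 0 with RLE, upper quartile or total-count scaling, without the low-count filter, with limma voom, glmTreat or the epithelium marker covariate, or with the length trend removed. It was 11 without the robust fit, 12 with the stricter filter and 17 with the stromal marker covariate. It was 92 with the immune marker covariate, 190 with a surrogate variable, 519 with DESeq2 and 1994 with voom and sample quality weights. These last settings kept all 11 genes. At an unadjusted p under 0.05 edgeR gave 1702 genes, 824 higher and 878 lower, where 796.5 would be expected by chance. With single libraries left out this count ran from 1041 without saline replicate 2 to 2479 without saline replicate 1. The other tools gave 258 genes with DESeq2, 0 with limma voom and 669 with limma voom with sample quality weights at an adjusted p under 0.05. DESeq2 called all 12 genes above, and so did voom with sample quality weights. In counts simulated for this comparison on 15930 genes with 200 changed, edgeR called 6 of 100 genes changed 2-fold, 48 of 100 changed 4-fold and 2 unchanged genes, and DESeq2 called 20, 67 and 51. Voom with sample quality weights called 4, 44 and 1. With no gene changed, DESeq2 called 22 genes, and edgeR and voom with sample quality weights 0. The simulated genes were independent and no library was made noisier than another. These counts therefore do not show how often each tool makes false calls in the real libraries. Voom with sample quality weights was not run on the other splits of the libraries. The simulated DESeq2 fit held only the filtered genes, while its 258 real calls came from 23735 genes.

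Direction went with gene length. Among the 3985 shortest genes the median log2 fold change was 0.21, with 318 genes higher and 74 lower at an unadjusted p under 0.05 by edgeR. Among the 3981 longest it was -0.19, with 97 higher and 484 lower. The 12 genes named above followed this trend in part. The lower ones were 5400 (ZNF217) to 12412 (ZNF462) bases long. The higher ones were 761 (PYCARD) to 2826 (GSDMD) bases long, apart from KCNQ5 at 6144. Spearman's rho of the log2 fold change with gene length, across genes, which are not independent replicates, was -0.25. With single libraries left out, rho was computed on another measure, the difference between group means of log2 CPM. It ran from -0.29 without saline replicate 2 to -0.15 without saline replicate 1. The slope of log2 CPM on log2 gene length was 0.101 ± 0.041 (SD, n = 7) after bacteria and 0.198 ± 0.046 (SD, n = 3) after saline, with an exact permutation p of 0.00833, two-sided, the smallest that 120 splits allow.

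**Figure D2:**
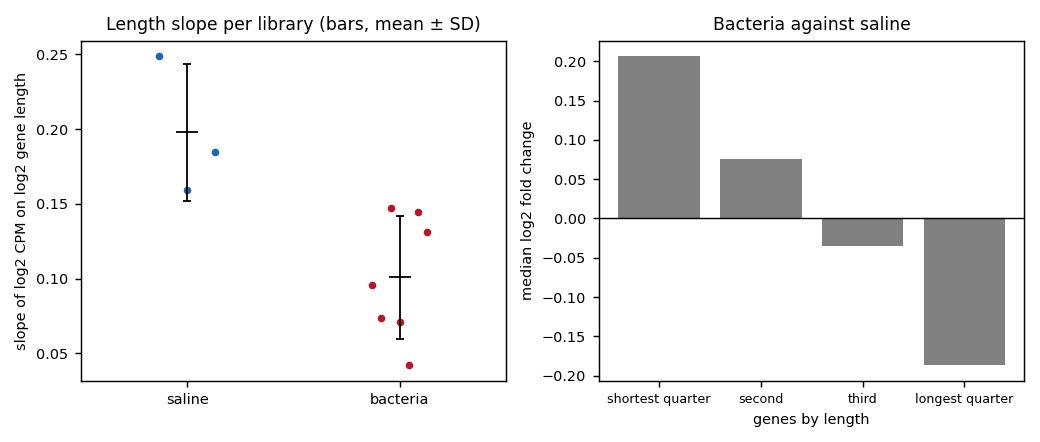
Left, the slope of log2 CPM on log2 gene length in each library, with the mean and SD of 3 saline and 7 bacteria libraries; right, the median log2 fold change of bacteria against saline for genes in 4 classes of length. All saline slopes lie above all bacteria slopes, and the median runs from 0.21 in the shortest to -0.19 in the longest genes.

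The groups did not separate as a whole. The difference between bacteria and saline held 14.8% of the variance of log2 CPM, where 11.1% would be expected by chance, with an exact permutation p of 0.225. The first principal component held 42.1% of the variance and the second 16.7%. The groups overlapped on both. Their means on the first gave an exact permutation p of 0.475. On the second the mean was higher after bacteria (exact permutation p = 0.0167), which did not pass when adjusted over 4 components (0.0667), and bacteria replicate 3, at -22.7, lay below saline replicate 3, at -18.3. Saline replicate 2 lay apart on the second component, at -89.6. In that library 16.5% of counts came from mitochondrially encoded genes (95% Wilson interval 16.489% to 16.525%, counting error alone). The mitochondrial share was 4.15 ± 1.61% (SD, n = 7) after bacteria and 9.32 ± 6.33% (SD, n = 3) after saline, with an exact permutation p of 0.0417. Without saline replicate 2 the saline mean was 5.73 ± 1.61% (SD, n = 2) and the exact permutation p 0.278. That p was 0.0595 without bacteria replicate 1, 2, 3, 4 or 6, 0.0556 without saline replicate 1 and 0.0833 without saline replicate 3. It was 0.0357 without bacteria replicate 5 and 0.0238 without bacteria replicate 7.

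**Figure D3:**
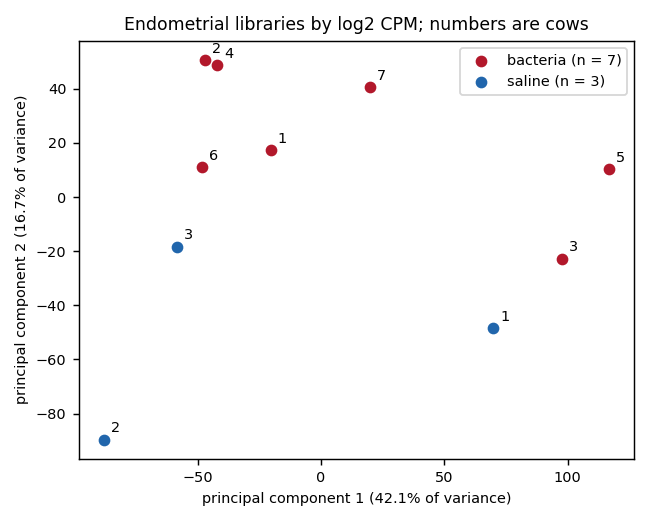
Libraries on the first 2 principal components of log2 CPM, numbered by cow within each group of 7 bacteria and 3 saline libraries. The first component holds 42.1% and the second 16.7% of the variance, and saline replicate 2 lies at -89.6 on the second.

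Genes of the motile cilium, the machinery that beats on ciliated epithelial cells, were higher after bacteria as a list by camera with a preset correlation (adjusted p = 3.98e-14), and not with an estimated correlation (adjusted p = 0.663). Of 87 measured members, 83 were fitted higher, with a median log2 fold change of 1.26. By edgeR no member passed alone, and 0 passed when adjusted over the list alone, with 23 at an unadjusted p under 0.05. CFAP157, a ciliary protein gene, had a log2 fold change of 2.76 (SE 0.80) and CCDC113 of 2.34 (SE 0.77). CFAP157 lay near the floor after saline, at 0.297 ± 0.128 CPM (SD, n = 3). The mean level of the list was 0.50 log2 CPM in saline replicate 2 and between 2.06 and 4.16 in the other libraries. With the level of epithelium markers as a covariate the median was 0.61 (adjusted p = 1.51e-07). All 16 markers of ciliated epithelium are also members of the motile cilium list, so their result is no separate support. They were higher by the same test with a preset correlation, with a median of 1.45 and an adjusted p of 8.51e-07, which became 0.828 with an estimated correlation. That median was 0.96 without saline replicate 2 and 0.68 with the epithelium covariate (adjusted p = 0.000685). TPPP3 had 171 ± 120 CPM (SD, n = 7) after bacteria and 37.2 ± 29.8 CPM (SD, n = 3) after saline.

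Interferon-stimulated genes were high in the endometrium of 2 cows given bacteria and in no other cow. ISG15, a ubiquitin-like modifier induced by type I interferon, stood at 1214 CPM in bacteria replicate 2 and 796 CPM in bacteria replicate 4, and between 3.84 and 18.1 CPM in the other 8 libraries. MX1, an antiviral GTPase, stood at 997 and 834 CPM in those libraries and at no more than 136 CPM in the others. For 48 of 57 measured members both libraries lay above all 8 others. The list rose after bacteria by camera with a preset correlation, with 53 members fitted higher, a median log2 fold change of 1.16 and an adjusted p of 8.84e-05. The adjusted p was 0.686 with an estimated correlation. Without those 2 libraries, left out after the data were seen, the median was -0.00 and the adjusted p 0.727. The call also ended with the epithelium covariate (median 0.71, adjusted p = 0.111). CXCL10, a chemokine, had a log2 fold change of 2.50 (SE 0.68) and an adjusted p of 0.317 with edgeR. Bacteria replicate 4 also held transcripts of genes of the trophoblast, the outer layer of the conceptus. TKDP1, a trophoblast Kunitz domain protein gene, had 1719 counts there and 0 in each other library. PAG11, a pregnancy-associated glycoprotein gene, had 355 counts there and 0 in each other library. IFNT2, an interferon tau gene, had 283 counts there and at most 6 elsewhere. These genes belong to families of related genes, and reads may be split between those members that are nearly identical.

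**Figure D4:**
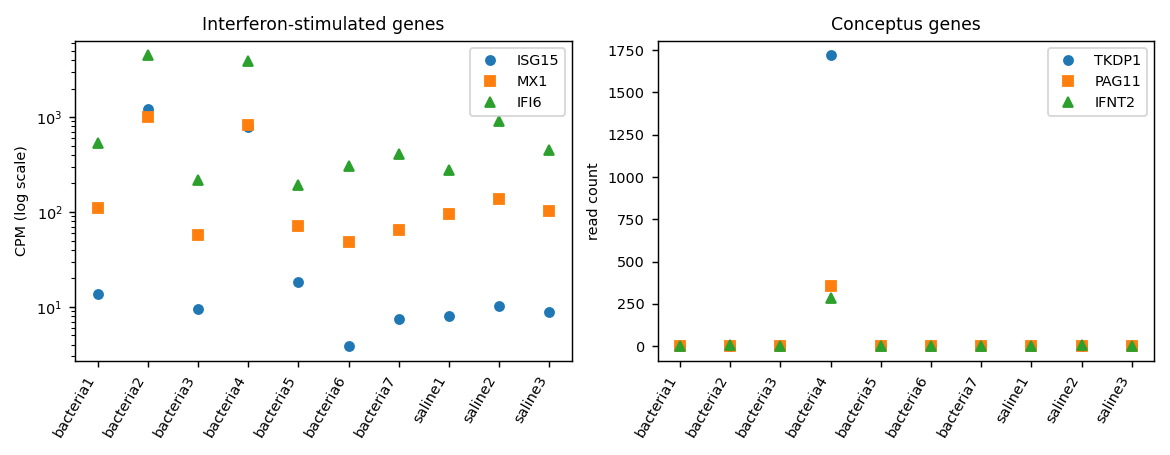
Left, CPM on a log scale of 3 interferon-stimulated genes in each library; right, read counts of 3 conceptus genes. ISG15 lies at 1214 CPM in bacteria replicate 2 and 796 CPM in bacteria replicate 4 and at or under 18.1 CPM elsewhere, and TKDP1 has 1719 counts in bacteria replicate 4 alone.

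By camera with a preset correlation, nuclear genes of oxidative phosphorylation, which make the respiratory chain, were slightly higher after bacteria as a list, and the mitochondrially encoded ones lower. With an estimated correlation neither list passed (adjusted p = 0.663 and 0.828). No nuclear member passed alone by edgeR. All 76 nuclear members were fitted higher, with a median log2 fold change of 0.30 and an adjusted p of 4.13e-10. Without saline replicate 1 the median was 0.13 and the preset adjusted p 0.0775, while without saline replicate 2 the median was 0.59. Without bacteria replicates 2 and 4 it was 0.10 (adjusted p = 0.00228). NDUFA12, a subunit of complex I, had a log2 fold change of 1.52 (SE 0.52). All 13 mitochondrially encoded genes were fitted lower, with a median of -1.27 and an adjusted p of 5.01e-08. That median was -0.40 without saline replicate 2. By edgeR, 13 passed when adjusted over the list alone and 0 over all genes. ATP6 had a log2 fold change of -1.34 (SE 0.46), which was -0.50 without saline replicate 2. Ribosomal protein genes were higher by the same test, with 53 of 54 fitted higher, a median of 0.33 and an adjusted p of 6.73e-10. It became 0.940 with an estimated correlation, and without saline replicate 1 the median was 0.09 and the preset adjusted p 0.270, while without saline replicate 2 the median was 0.56. It was 0.53 with the epithelium covariate. With each library's trend on gene length removed, the median was 0.14 for the nuclear list (adjusted p = 0.0489) and 0.15 for the ribosomal list (adjusted p = 0.0228).

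Inflammatory cytokines and chemokines, and antimicrobial and acute phase proteins, rose as lists by camera with a preset correlation, and no member passed alone by edgeR. Both had an adjusted p of 0.663 with an estimated correlation. Pattern recognition and NF-kB signalling (adjusted p = 0.519) and complement (adjusted p = 0.115) did not pass camera with a preset correlation. Of 43 inflammatory cytokines and chemokines, 32 were fitted higher, with a median log2 fold change of 0.44 and an adjusted p of 0.0223 by camera with a preset correlation. Of 32 antimicrobial and acute phase proteins, 24 were fitted higher, with a median of 0.63 and an adjusted p of 0.0223. In both lists 0 members passed when adjusted over the list alone by edgeR, with 6 and 3 at an unadjusted p under 0.05. CSF3, the granulocyte colony-stimulating factor gene, had 6.16 ± 3.69 CPM (SD, n = 7) after bacteria and 0.644 ± 0.579 CPM (SD, n = 3) after saline, and the mucosal chemokine gene CCL28 a log2 fold change of 1.83 (SE 0.54). PIGR, which carries IgA across epithelium, had 718 ± 316 CPM (SD, n = 7) and 213 ± 122 CPM (SD, n = 3), and LTF, the lactoferrin gene, a log2 fold change of 1.43 (SE 0.69), which was 1.03 without saline replicate 2 and 2.62 without saline replicate 1. The cytokine call ended without bacteria replicate 1 (adjusted p = 0.0505; median 0.49), bacteria replicate 5 (0.0899; median 0.18), bacteria replicate 7 (0.111; median 0.40) or saline replicate 3 (0.138; median 0.52). Its median was 0.93 without saline replicate 1 and 0.28 without saline replicate 2. It also ended with the epithelium covariate (0.375; median 0.53), the stromal covariate (0.0944; median 0.18), the immune covariate (0.118; median 0.31) or a surrogate variable (0.101; median 0.44). The antimicrobial call ended without bacteria replicate 1 (0.0780; median 0.50), bacteria replicate 5 (0.0899; median 0.58), bacteria replicate 7 (0.153; median 0.40), saline replicate 2 (0.137; median 0.67) or saline replicate 3 (0.397; median 0.58), and its median was 1.66 without saline replicate 1. It ended too with the epithelium covariate (0.968; median 0.14), the immune covariate (0.118; median 0.67), a surrogate variable (0.0905; median 0.66) or the length trend removed (0.0946; median 0.45).

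**Figure D5:**
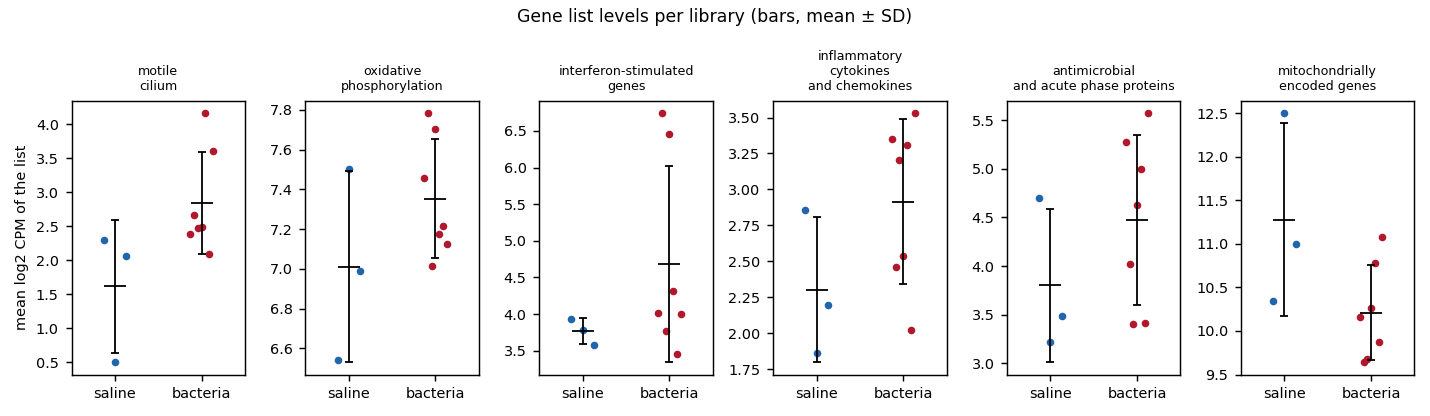
Mean log2 CPM of 6 gene lists in each library, with the mean and SD of 3 saline and 7 bacteria libraries. The groups overlap in each list; the motile cilium list lies at 0.50 in saline replicate 2 and the interferon-stimulated list is highest in 2 bacteria libraries.

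Of 20 gene lists, 5 passed camera with a preset correlation. With an estimated correlation and with fry, 0 passed after adjustment, and with the level of epithelium markers as a covariate 2 passed camera. By an exact permutation test of the mean level per library the lowest raw p was 0.0583, of the motile cilium list, and 0 passed. That test could hardly pass, since a single list could reach an adjusted p of 0.167 at the smallest and 4 lists would have to reach the smallest p together. Among 44 genes of pattern recognition and NF-kB signalling, with a median log2 fold change of -0.08 (0.01 without saline replicate 2), 2 passed when adjusted over the list alone by edgeR. These were PYCARD, and IKBKB, a kinase of NF-kB activation, with a log2 fold change of -0.85 (SE 0.17). GSDMD passed within the cell death list and LPIN1 within the lipid and cholesterol list, each adjusted over the list alone. By edgeR none of these 4 genes passed over all genes. The prostaglandin list had a median of 0.24 (0.13 without bacteria replicate 6 and 0.42 without saline replicate 2), and PTGES, a prostaglandin E synthase, a log2 fold change of 2.66 (SE 0.76). Antigen presentation had a median of 0.31 and passed camera with a preset correlation without bacteria replicate 3 (adjusted p = 0.0379), bacteria replicate 6 (0.00844) or saline replicate 2 (0.0269). Complement had a median of 0.56, which was 0.31 without saline replicate 3 and 1.13 without saline replicate 1, and passed without bacteria replicate 6 (0.00844). Endoplasmic reticulum stress had a median of 0.19, which was 0.05 without bacteria replicate 5 and 0.08 without saline replicate 3, and passed without bacteria replicate 3 (0.0258) or saline replicate 1 (0.0215; median 0.41). The cell cycle list went both ways, with a median of 0.56 that turned to -0.52 without bacteria replicate 3, where it passed as lower (0.0463), and was 1.31 without saline replicate 1, where it passed as higher (0.0215). It was 0.17 without saline replicate 3. Lipid metabolism had a median of -0.08, which ran from -0.24 without saline replicate 1 to 0.00 without saline replicate 3, and passed as lower without bacteria replicate 6 (0.0197). Glycolysis had a median of 0.16, which was 0.27 without saline replicate 1. Hormone receptors had a median of -0.16 and transporters of -0.15, both -0.00 without saline replicate 2, and transporters -0.32 without bacteria replicate 6. Cell junctions had a median of -0.17, which turned to 0.06 without saline replicate 1, and cell death of 0.00, which was 0.21 without saline replicate 1. In 3 lists the median and the direction of the test or the mean differed in sign. Extracellular matrix genes had a median of 0.40 and a camera direction of lower. That median turned to -0.16 without bacteria replicate 3, where the list passed as lower (0.0358), and was 0.08 without bacteria replicate 5 and 0.80 without saline replicate 1. The receptivity list had a median of -0.06 (-0.13 without bacteria replicate 3 to 0.15 without saline replicate 1) and a mean of 0.22. The growth factor list had a median of -0.08 (-0.11 without bacteria replicate 5 to 0.58 without saline replicate 1) and a mean of 0.09. PTCH1, the hedgehog receptor of the receptivity list, had a log2 fold change of -1.19 (SE 0.29).

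Among 15 lists of markers, most of them of cell types that a brush can collect, 4 passed camera with a preset correlation, and 0 passed with an estimated correlation or with fry. The ciliated epithelium markers among them all belong to the motile cilium list above. By an exact permutation test of marker levels, squamous epithelium of the cervix or vagina and ciliated epithelium had the lowest raw p, each 0.0417. Both had an adjusted p of 0.292 in that test. No list passed that test after adjustment, but a single list could reach 0.125 at the smallest and 3 would have to reach the smallest p together. By camera with a preset correlation squamous markers were higher, with 12 of 13 fitted higher, a median log2 fold change of 1.99 and an adjusted p of 0.00341. It became 0.828 with an estimated correlation. Without saline replicate 3 the median was 1.15 and the preset adjusted p 0.0765, and the median was 0.73 without bacteria replicate 5 and 3.39 without saline replicate 1. With the epithelium covariate the median was 1.15 (adjusted p = 0.066), and with the stromal covariate 1.30. KRT14, a basal keratin gene, had 6.70 ± 4.52 CPM (SD, n = 7) after bacteria and 0.975 ± 0.588 CPM (SD, n = 3) after saline. The luminal and glandular epithelium list had a median of -0.09, which ran from -0.15 without bacteria replicate 2 to 0.01 without saline replicate 2. In it FOXA2, a transcription factor of uterine glands, passed when adjusted over the list alone, with a log2 fold change of 1.95 (SE 0.43), and not over all genes (adjusted p = 0.261, edgeR). Stromal fibroblast markers had a median of 1.17, which was 0.51 without bacteria replicate 5 and 0.56 without bacteria replicate 3, and passed camera without bacteria replicate 6 (adjusted p = 0.0337). The medians of several lists turned without bacteria replicate 5. Smooth muscle and pericyte markers turned from 1.65 to -0.02 and B and plasma cell markers from 0.70 to -0.44. Neutrophil markers turned from 0.32 to -0.15 and erythrocyte markers from 0.45 to -0.15. Only 3 of 13 erythrocyte markers were measured. Their median was the value of a single gene, HBQ1 with all libraries and HBB without bacteria replicate 5. Without saline replicate 1 the B and plasma cell median was 1.24 and the neutrophil median 1.01, and without saline replicate 2 the smooth muscle and pericyte median was 1.07. Macrophage and monocyte markers had a median of 0.28, which ran from -0.18 without bacteria replicate 3 to 0.77 without saline replicate 1, and endothelial markers of 0.14, which ran from -0.14 without saline replicate 2 to 0.29 without bacteria replicate 2. T and NK lymphocyte markers had a median of 0.25 and passed as higher without bacteria replicate 1 (0.0351), bacteria replicate 2 (0.0352) or saline replicate 2 (0.0224; median 0.51). Mast cell, basophil and eosinophil markers, of which only 4 of 18 were measured, had a median of -0.53, which was -0.11 without saline replicate 3. Dissociation stress genes had a median of 0.04, which ran from -0.39 without bacteria replicate 1, where they passed as lower (0.0131), to 0.46 without saline replicate 2, and in cows 1 to 3 of each group alone they passed as higher (0.00013; median 0.80).

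The receptors that time the bovine cycle showed no call by edgeR. ESR1, the estrogen receptor, had 143 ± 55.5 CPM (SD, n = 7) after bacteria and 120 ± 40.5 CPM (SD, n = 3) after saline, and its log2 fold change of 0.25 turned to -0.00 without saline replicate 2. PGR, the progesterone receptor, had a log2 fold change of 0.54 (SE 0.38), which was 0.30 without bacteria replicate 5 and 0.71 without saline replicate 1. OXTR, the oxytocin receptor, had 106 ± 87.6 CPM (SD, n = 7) and 327 ± 250 CPM (SD, n = 3), and its log2 fold change ran from -2.03 without saline replicate 3 to -0.83 without saline replicate 1. PTGS2, the inducible cyclooxygenase, had a log2 fold change of -0.92 (SE 1.13), which turned to 0.30 without saline replicate 2. TLR4, the endotoxin receptor, had a log2 fold change of -0.26 (SE 0.23), which turned to 0.00 without saline replicate 2. The cytokine genes IL1B and CXCL8 had log2 fold changes of 0.44 (SE 0.79) and 0.63 (SE 0.92), which turned to -0.12 and -0.11 without bacteria replicate 5. SERPINA14, the uterine milk protein gene, had a log2 fold change of 0.75 (SE 1.65), which was 0.02 without bacteria replicate 2 and 3.22 without saline replicate 2.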

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

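The tests of the interferon pattern and the tests without saline replicate 2, with the readings of both, were chosen after the results were seen; the others were fixed before theirs. Of 127 values examined in the 7 bacteria libraries, 6 had a library far from its neighbours, where chance gives about 6.3. The hormone receptor list reached 4.57 log2 CPM in bacteria replicate 7, the B and plasma cell markers 3.90 in bacteria replicate 5, and PYCARD was lowest in bacteria replicate 1, at 3.11. ABCG1 reached 7.95 log2 CPM in bacteria replicate 7, KIT was lowest in bacteria replicate 5, at 1.49, and the globin gene HBB reached 7.65 in bacteria replicate 5.

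Genes left out of the tests by the low-count filter carried a signal above the saline libraries in bacteria replicate 4. Summed counts there were 583 for interferon tau, 578 for the pregnancy-associated glycoproteins and 2223 for the trophoblast Kunitz domain proteins. In a saline library they were at most 22, 2 and 0. The interferon-stimulated list does not show a rise shared by all infused cows, since its median log2 fold change was -0.0032 without bacteria replicates 2 and 4. A candidate explanation is that these cows carried a conceptus, whose trophoblast secretes interferon tau: the 3 families summed to 3384 counts in bacteria replicate 4, so that conceptus cells may have been in that brush. In bacteria replicate 2 they summed to 21 against up to 24 in a saline library, 22 of it interferon tau, but the pregnancy-associated glycoproteins had 11 counts there, 7 in bacteria replicate 6 and at most 2 in a saline library, so that these few counts leave a small amount of conceptus material open, as they do an exposure of the cow to a conceptus or to another source of interferon. The labels give no pregnancy status, and 46.7% of splits would place both libraries among the 7 by chance.

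The motile cilium list had a median log2 fold change of 1.26, which was 0.61 with the epithelium covariate. The length trend was small beside it, with a median of 0.21 in the shortest and -0.19 in the longest genes. Its removal could therefore hardly lower the list's median, which was then 1.29. A trend of that size does not make up the rise of the list. Whether saline replicate 2 accounts for it alone stays open: without that library the median was 0.936 and the preset camera adjusted p 1.25e-07, but that p takes the members as nearly independent, and the mean levels differed by 0.659 log2 CPM, less than the SD of 0.754 among cows given bacteria, with an exact permutation p of 0.222 over 36 splits, two-sided. The members moved together from cow to cow within groups, with a median pairwise correlation of 0.764 against 0.033 on average in random lists of like expression, so that a different share of ciliated cells in the brushed material may account for the pattern, as may a programme that these genes share. Chance cannot be excluded either: 18 of 100 splits gave as small a camera p as the real 1.99e-15, the smallest of the others being 4.79e-41. Bacterial infusion stays among the open explanations.

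Short genes were higher and long genes lower after bacteria. The trend was present outside the 130 ribosomal protein and oxidative phosphorylation genes, with a rho of -0.241 without them. Leaving out so few of the 15930 tested genes could hardly have changed rho, so this says little about their part in it. The slopes of log2 CPM on log2 gene length separated the groups, with an exact permutation p of 0.00833. They restate by library the difference already seen in the fold changes. That p therefore cannot exclude biases of single libraries that fell along the groups by chance. The gap was narrow, with saline replicate 2 at 0.160 and bacteria replicate 3 at 0.147, and saline replicate 1 stood highest at 0.249. RNA quality or library preparation that differed with the group stays open, since the labels give neither, and so does the infusion.

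The mitochondrially encoded genes had a median log2 fold change of -0.3954 without saline replicate 2 and of -1.36 with the length trend removed.

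With a real count of 0 genes by edgeR, 100 of 100 splits reach it by construction, so their number says nothing about chance. The highest other was 3172 genes when bacteria replicates 3 and 5 and saline replicate 1 were set against the rest, which points to a structure of the samples. Chance cannot be excluded for the other counts. DESeq2's 258 genes were reached by 9 of 100 splits, the highest other being 4303. The 1702 genes at an unadjusted p under 0.05 were reached by 10 of 100, the highest other being 5554, and 5 gene lists by 76 of 100, the highest other being 12.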

How the results depend on the processing

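The settings that leave out bacteria replicates 2 and 4, remove the length trend, permute list levels or test lists in cows 1 to 3 without the block were added after the data were seen. The count of 0 genes with edgeR (1702 at an unadjusted p under 0.05) stayed 0 under other scalings and filters, limma voom, glmTreat and each library left out. It became 258 (174 higher, 84 lower) with DESeq2, 669 (264 higher, 405 lower) with voom and sample quality weights, 41 (16 higher, 25 lower) with a surrogate variable, 26 (16 higher, 10 lower) with the immune marker covariate and 11 (9 higher, 2 lower) at an adjusted p under 0.1; the cause was not tested. The count of 5 gene lists became 0 with an estimated correlation, 0 with fry, 0 with the exact permutation of levels, 2 with the epithelium covariate and 8 in the replicate block, which held only cows 1 to 3 of each group and left out bacteria replicates 4 to 7, against 6 in those cows without the block, and lay between 3 and 9 with single libraries left out; the cause was not tested. Cow numbers 1 to 3 occur in both groups and were taken to name different animals, since each cow gave 1 library. Deviations correlated at -0.323, 0.326 and -0.277 between equal numbers, and not every library went best with its own number, which cannot settle identity. The block gave 0 genes, as did the same cows without it. The antimicrobial and acute phase list did not pass in those cows with the block (median 0.16, adjusted p = 0.221) or without it (0.49, 0.184). Squamous markers had medians of 1.04 and 0.45 there, and without the block the cytokine list had 0.25, the motile cilium list 0.67 and ciliated markers 0.88. The exact test of marker levels passed 0 lists in each setting, which says nothing of stability: 9 lists would have to reach the smallest p together with a saline library left out. By camera with a preset correlation the 4 marker lists became 3 to 6 with single libraries left out, 3 with the epithelium covariate and 6 in the block. In the block complement (adjusted p = 0.0312), prostaglandin (0.0304), cell cycle (0.000554), stromal fibroblast (1.36e-05) and dissociation stress genes (4.27e-05; median 0.77) also passed as higher and lipid metabolism (0.0312) as lower. In those cows without the block cell cycle (0.0285), stromal fibroblast (0.0128) and dissociation stress genes (0.00013) passed as higher and lipid metabolism (0.0192) as lower. Other lists passed as higher without bacteria replicates 2 and 4 (complement, 0.0435; cell cycle, 0.0229; stromal fibroblast, 0.0234), with the stromal covariate (antigen presentation, 0.0334; prostaglandin, 0.0406), a surrogate variable (prostaglandin, 0.0480), total-count scaling (antigen presentation, 0.0417) or no filter (endoplasmic reticulum stress, 0.0406; T and NK lymphocyte, 0.0456), and as lower without bacteria replicates 2 and 4 (lipid metabolism, 0.0229) or with the stromal covariate (extracellular matrix, 0.00895). The variance between groups lay between 10.64% and 22.1% with single libraries left out. The interferon-stimulated list turned to -0.0032 without bacteria replicates 2 and 4, and MX1 to -0.69. In the replicate block C5 turned to 0.055, IL1B to -0.093 and CXCL8 to -0.065; with limma voom IL1B turned to -0.12, CXCL8 to -0.071 and SERPINA14 to -0.58; with DESeq2 HBB turned to -0.10. Over 88 named genes under RLE scaling, DESeq2, limma voom, the block, without bacteria replicates 2 and 4 and with each library left out, 1276 of 1320 values kept direction and side of the threshold, 27 passed, all with DESeq2, and 17 turned. Outside that tally voom with sample quality weights called 29 of these genes, a surrogate variable 12 and the immune covariate 8. With single libraries left out, log2 fold changes ranged from -3.33 to 0.81 for C5, -1.80 to 0.045 for ITGA2, -0.94 to 0.32 for GATA2, -0.15 to 3.67 for HBB, -0.0017 to 0.52 for ESR1, -1.58 to 0.30 for PTGS2, -0.12 to 0.76 for IL1B, -0.11 to 1.20 for CXCL8 and -0.40 to 0.0048 for TLR4; the cause of these turns was not tested. At this depth 15930 of 34750 genes passed the low-count filter. The conceptus genes did not, although TKDP1 had 1719 counts in bacteria replicate 4, since the filter asks for counts in more than 1 library.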

Other observations

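The main axis of difference between the cows went with markers of macrophages and monocytes, neutrophils, B and plasma cells, stromal fibroblasts, and smooth muscle and pericytes. Over the 10 libraries, the first principal component correlated with the level of macrophage and monocyte markers (Pearson r = 0.952, permutation p = 0.00017, adjusted 0.00128; Spearman rho = 0.879, permutation p = 0.00153, adjusted 0.0115). Without bacteria replicates 3 and 5, the 2 farthest from the median, r was 0.932. Neutrophil markers gave r = 0.92 (permutation p = 0.00036, adjusted 0.0018; rho = 0.806, permutation p = 0.00707, adjusted 0.0262) and 0.911 without those 2. Stromal fibroblast markers gave r = 0.869 (permutation p = 0.00104, adjusted 0.0033; rho = 0.794, permutation p = 0.00873, adjusted 0.0262) and 0.612 without them. Smooth muscle and pericyte markers gave r = 0.912 (permutation p = 0.00012, adjusted 0.00128; rho = 0.806, permutation p = 0.00716, adjusted 0.0262) and 0.762 without them, and B and plasma cell markers r = 0.818 (permutation p = 0.0011, adjusted 0.0033; rho = 0.879, permutation p = 0.00147, adjusted 0.0115) and 0.761. Ciliated epithelium markers passed by rank alone, with rho = 0.758 (permutation p = 0.0147, adjusted 0.0368) and r = 0.665 (permutation p = 0.0266, adjusted 0.0665), and r = 0.61 without those 2. The other immune lists did not pass. T and NK lymphocyte markers gave r = 0.427 (permutation p = 0.21, adjusted 0.35; rho = 0.309, permutation p = 0.384, adjusted 0.576) and -0.092 without those 2, and mast cell, basophil and eosinophil markers r = 0.283 (permutation p = 0.425, adjusted 0.49; rho = -0.006, permutation p = 1, adjusted 1) and -0.189. In all, 15 marker lists were related to this component. The markers are part of the values the component was made from.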
